A study of Mus musculus with 4 samples.

How the data were processed

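Hearts of Postn-MCM/R26tdTO mice, in which tamoxifen switches on the red reporter tdTomato in cells that express Postn, were infarcted by permanent ligation of the left anterior descending artery. The infarcted muscle was injected once with 28 µL of retrovirus. The virus carried an empty construct (Empty), PHF7, PHF7 with Tbx5 (PT), or PHF7 with Mef2c and Tbx5 (PMT), and hearts were taken 4 weeks after infarction, with tamoxifen chow throughout. Per the labels' protocols, 1 to 3 snap-frozen hearts were pooled per condition, and nuclei stained for the nuclear pore complex were sorted and used for paired RNA and chromatin accessibility libraries (10x multiome). Each group is 1 pooled library, so there are 4 libraries in all and no replicates. The control library is labelled Empty, while the name of its deposited matrix says GFP, a difference the sources used here do not explain.

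The deposited matrices hold counts per nucleus barcode, made by the authors with Cell Ranger ARC 2.0.0 on mm10 to which 3 sequences (Ai9_SV40, tdTomato_Ai9 and hPHF7) had been added. The 32288 gene features hold counts of unique molecular identifiers (UMIs). The peak features hold counts of transposase cut sites in peaks called separately in each library, so a fragment inside a peak gives 2 counts, and accessibility intervals used a count divided by 2. Between 16.7 and 20.0% of the nonzero peak values were odd. The files at hand hold no cell annotation, fragment files or reads. Gene positions came from a RefSeq table of GRCm38, which has the coordinates of mm10, and 26660 gene names (82.6%) had one.

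Nuclei were kept with at least 500 UMIs, 300 detected genes, 1000 peak counts and under 5% mitochondrial UMIs, which left 9164 of 11364 barcodes. Scrublet, as run through scanpy, called 10 of these (0.109%) as doublets at its automatic threshold and was taken not to have worked. Instead, the nuclei with the highest scores were removed per library, at 0.8% of nuclei per 1000 nuclei. This took out 191 nuclei and left 8973. Counts were log-normalised, and nuclei were clustered on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1.

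Clusters were named from 15 marker lists fixed before the data were examined. A marker counted as on in a cluster with at least 20 UMIs there and at least 1/3 of its level in its highest cluster. A name needed at least 3 markers on and 60% of the list, and clusters with 2/3 of the markers of an unrelated class on, or with another class leading their top 10 genes, stayed unnamed. These thresholds were set after the clusters had been seen. A class is called X-like, since it rests on RNA markers alone.

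RNA counts were summed per class and library and scaled to CPM by the total UMIs of the class, with 0.5 counts added before a ratio was taken. Ratios carry exact Poisson (conditional binomial) 95% intervals and shares exact Clopper-Pearson 95% intervals, both of which cover counting error only. They leave out differences between hearts and between library preparations. Since nuclei are not replicates, no test between groups was run and no p-value is given. Each treated library was compared with Empty, PT with PHF7, and PMT with PT. Unless said otherwise, a single gene's value without a unit is a ratio where a 95% interval follows. Where none follows it is a log2 ratio. Bounds set by 0 counts are ratios.

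The median log2 ratio of each list over members with at least 100 UMIs in the compared pair was placed among 10000 random lists of the same size, matched on expression in 20 bins, as a description of these libraries. Medians needed at least 3 members. The 16 lists, also fixed before the data were examined, cover sarcomere, calcium and ion handling, cardiac transcription regulators, fetal and stress genes, fatty acid oxidation and mitochondria, activated, late scar and resting fibroblasts, collagen and matrix, TGF-beta and YAP targets, cell cycle, inflammation, interferon stimulated genes, angiogenesis and hypoxia, immediate early and dissociation stress genes, and a neural and skeletal muscle control. The marker lists were run as lists too. Of the 204 genes of the 16 lists, 203 were in the files.

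Genes were named by a rule fixed before the data were examined. In fibroblast-like nuclei it takes the 8 largest and 8 smallest ratios per comparison with Empty, and in cardiomyocyte-like nuclei the 5 largest and 5 smallest, among genes with at least 100 UMIs whose interval excludes a ratio of 1.5. It adds the 2 highest and 2 lowest members of each list and always Phf7, Tbx5 and Mef2c, and leaves out mitochondrial, ribosomal, unnamed and sex-linked genes. For accessibility in fibroblast-like nuclei it takes the 5 largest and 5 smallest ratios. Some genes that the rule names are not reported here. Genes named outside this rule are said to have been chosen after their values were seen. Where a library had 0 counts, the ratio was bounded with a floor of 3 counts.

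Peaks of the 4 libraries were merged at an overlap of at least 1 bp, and only regions with a peak in all 4 were compared. The planned promoter windows need transcription start sites and strands, which the files and the table lack. Accessibility was therefore summed over all shared regions within 1 kb of a gene's body and scaled to the total in shared regions (CPM). The share of nuclei with a sarcomere UMI was taken after each nucleus was thinned to 1000 UMIs. Nuclei were called female or male from at least 2 UMIs of Xist or of 4 Y-linked genes with 95% of one kind, and as holding both kinds from at least 4 such UMIs in between. Female and male nuclei of one library must come from different hearts, so each such set of at least 20 nuclei is called a heart unit. A list median over a heart unit carries a bootstrap interval over its genes (2000 draws). Values of cardiomyocyte-like nuclei were also taken without clusters 13 (0 nuclei in PMT) and 15, whose nuclei held 2.32 and 2.24 times the median UMIs of their libraries and often RNA of both sexes, a choice made after the data were examined.

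A simulation drew Poisson counts from the Empty profiles at the depths of these libraries, with 200 genes altered and no spread between nuclei or hearts. Intervals covered the set ratio for 95.3 to 96.2% of genes in fibroblast-like and 95.5 to 95.8% in cardiomyocyte-like nuclei. With such draws this checks the calculation alone. Altered genes under the UMI minimum were left out of the shares that follow. Among genes simulated at a ratio of 4, all intervals excluded 1.5. At a ratio of 2 the share was 22.9 to 78.0% in fibroblast-like and 80.0 to 86.0% in cardiomyocyte-like nuclei, and at a ratio of 0.5 it was 19.1 to 57.4 and 50 to 86.7%. At a ratio of 0.25 it was 54.0 to 100% in fibroblast-like nuclei, lowest in PMT, whose lower genes are therefore often missed.

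Before the data were examined, 34 alternatives were set, and 12 were added after. They covered cluster resolution, doublet removal, nucleus filters, clustering on peak counts, median-of-ratios scaling, count minimums, added counts, subtraction of free RNA, sex-called nuclei, thinning, windows and peak overlap. The planned free-RNA estimate from macrophage-like and endothelial-like nuclei was 52.7, 52.3, 61.9 and 23.6% in Empty, PHF7, PT and PMT, more than fibroblast-like nuclei could hold, and was capped at what these hold (10.8, 7.42, 7.35 and 6.60%). Sequence motifs were not analysed here, since no genome sequence was at hand. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, umap-learn 0.5.12 and matplotlib 3.10.9.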

Results

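Nuclei from infarcted mouse hearts were profiled for RNA and chromatin accessibility in the same nucleus after injection of retrovirus carrying an empty construct (Empty), PHF7, PHF7 with Tbx5 (PT) or PHF7 with Mef2c and Tbx5 (PMT). PHF7 is a chromatin reader of the PHD finger family, and Mef2c and Tbx5 are transcription factors of heart development. The hearts were taken 4 weeks after infarction, and each group is 1 library made from 1 to 3 pooled hearts, so there are no replicates. Intervals below cover counting error only, except those of medians over genes, which are bootstraps over those genes. Every difference is a difference between libraries. The libraries held 2998, 2519, 4015 and 1832 nucleus barcodes in Empty, PHF7, PT and PMT. They held 30.2, 35.8, 39.2 and 4.56 M UMIs, and 70.8, 66.2, 71.1 and 46.8 M peak counts. Median UMIs per barcode were 4594, 6250, 4734 and 1127.5, and median peak counts were 9041.5, 10560, 7441 and 9180. The PMT library was therefore shallow in RNA, with a like median and a lower total of peak counts. In PMT, mitochondrial transcripts took 2.67% of UMIs, against 0.348, 0.491 and 0.510% in Empty, PHF7 and PT. The RNA Gm42418, which overlaps ribosomal RNA sequence, took 7.05% there, against 0.425, 0.722 and 0.412%. After filtering and doublet removal, 2516, 2185, 3273 and 999 nuclei remained.

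RNA of sex-linked genes showed which hearts had been pooled. Xist, transcribed from the inactive X of females, stood at 0.869 CPM in Empty and at 960, 552 and 589 CPM in PHF7, PT and PMT. The Y-linked gene Ddx3y stood at 122, 54.4, 80.9 and 22.9 CPM. Of the nuclei called by sex, Empty held 1757 male and 0 female nuclei, PHF7 579 male and 905 female, PT 1219 and 808, and PMT 95 and 290. Nuclei with RNA of both sexes numbered 9, 372, 566 and 72. Each treated library thus held hearts of both sexes and Empty male hearts alone.

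Class shares address which cell types made up each infarcted heart after treatment. Cardiomyocyte-like nuclei made up 36.6% (95% interval 34.8 to 38.6) of nuclei in Empty, 54.6% (52.4 to 56.7) in PHF7, 52.4% (50.7 to 54.1) in PT and 81.6% (79.0 to 83.9) in PMT. Fibroblast-like nuclei were fewer in the treated libraries, at 25.6% (23.9 to 27.3) in Empty, 16.4% (14.9 to 18.0) in PHF7, 9.59% (8.61 to 10.7) in PT and 10.7% (8.86 to 12.8) in PMT. Endothelial-like nuclei made up 6.68, 4.58, 4.22 and 1.60%, macrophage-like nuclei 7.03, 4.71, 3.94 and 0.601% (3.86, 2.84, 1.92 and 0.501% at Leiden resolutions 0.5 and 2), and pericyte-like nuclei 4.25, 4.44, 3.54 and 2.80%. Adipocyte-like nuclei made up 7.0% (6.15 to 7.92) of PT and 0.366% of PHF7, with 0 of 2516 nuclei in Empty (at most 0.147%) and 0 of 999 in PMT (at most 0.369%). In PT this class held 79 of 1219 male and 0 of 808 female nuclei, and 126 of its 205 nuclei called by sex held RNA of both sexes. Clusters of the peak counts gave 3.24% (2.66 to 3.90) in PT, and at Leiden resolution 0.5 or with all deposited barcodes no cluster was named adipocyte. Lymphatic endothelial-like nuclei stood at 1.63, 1.78, 2.08 and 1.70% and smooth muscle-like nuclei at 0.477, 0.595, 1.10 and 0.501%. T or NK cell-like nuclei, whose cluster had the B cell genes Pax5 and Bank1 among its top genes, stood at 0.994, 0.641 and 1.83%, with 0 of 999 in PMT (at most 0.369%). At Leiden resolution 2 this gave 0.917% T or NK and 0.978% B cells in PT, and 0.320% each in PHF7, and with 3 times the doublets removed 0.420% T or NK cells in PT. Clusters left without a name held 16.7, 11.9, 14.3 and 0.501% of nuclei.

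The nuclei had been sorted, and the share of each class depends on which nuclei pass the filters, which kept 2569 of 2998 barcodes in Empty, 2225 of 2519 in PHF7, 3363 of 4015 in PT and 1007 of 1832 in PMT, where 28.5% were under the UMI minimum against at most 3.00% elsewhere. The share of fibroblast-like nuclei in PMT ranged from 2.95 to 20.9% across the settings tried, and finer clusters (Leiden 2) gave 7.05% in PHF7 and 4.71% in PT. Without all filters on nuclei at once, the cardiomyocyte-like share of PMT was 46.8%.

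**Figure D1:**
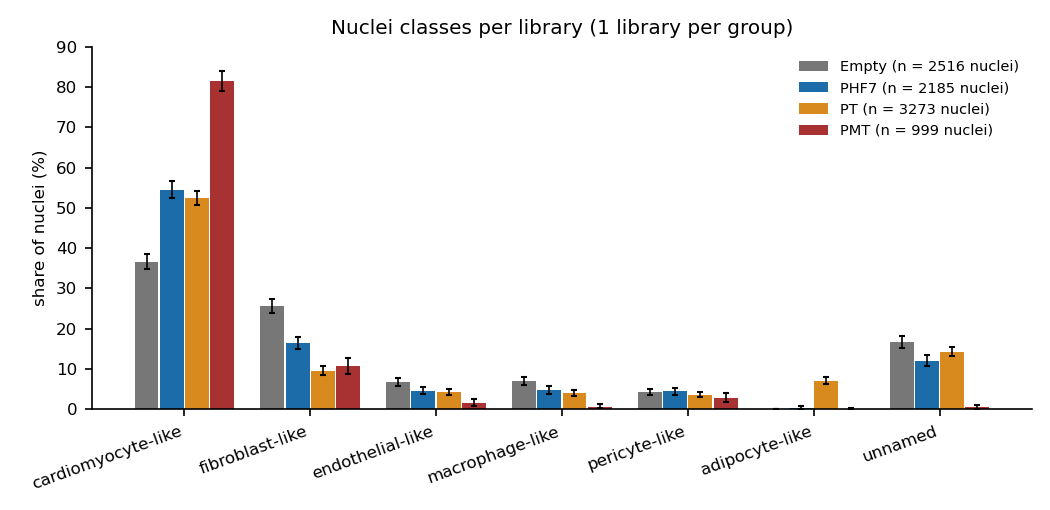
Share of nuclei (%) in each class for the 4 libraries, with bars from 0 and whiskers showing exact binomial 95% intervals (counting error only). Cardiomyocyte-like nuclei stand at 36.6% in Empty and 81.6% in PMT, and fibroblast-like nuclei stand at 25.6% in Empty and between 9.59 and 16.4% in the treated libraries.

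The delivered factors and the reporter were read next, to see which nuclei carried them. Tbx5 RNA in cardiomyocyte-like nuclei stood at 38.0 CPM (34.1 to 42.1) in Empty, 81.1 (76.3 to 86.2) in PHF7, 84.0 (79.2 to 89.0) in PT and 66.9 (57.9 to 76.8) in PMT, so it was higher in all 3 treated libraries, the library without delivered Tbx5 included. In fibroblast-like nuclei it stood at 1.35, 6.55 and 13.6 CPM in Empty, PHF7 and PT, from 3, 8 and 13 UMIs, and at 0 UMIs in PMT (under a floor of 24.8 CPM). The ratio to Empty was 4.41 (1.16 to 28.4) in PHF7 and 8.99 (2.78 to 55.3) in PT. Mef2c in fibroblast-like nuclei stood at 244, 196, 167 and 140 CPM, a ratio of 0.804 (0.687 to 0.937) in PHF7, 0.684 (0.569 to 0.816) in PT and 0.590 (0.332 to 0.927) in PMT. In cardiomyocyte-like nuclei Mef2c stood at 302, 354, 443 and 268 CPM. Transcripts of the added human PHF7 sequence numbered 2 in the PHF7 library and 0 in the others. Mouse Phf7 stood at 5.36, 6.87, 8.95 and 4.03 CPM over all nuclei, and in cardiomyocyte-like nuclei at 1.86 (1.14 to 3.24) and 3.06 (1.94 to 5.19) times Empty in PHF7 and PT. Mouse and viral transcripts of Tbx5 and Mef2c cannot be told apart in these counts. Viral transcripts may also go uncounted, where their end or coding sequence differs from that of the mouse gene. A low value of a factor therefore does not contradict the label of its library. RNA of tdTomato, the reporter switched on in cells that had expressed Postn, stood at 15.8, 9.0 and 7.35 CPM in fibroblast-like and 14.1, 11.5 and 12.2 CPM in cardiomyocyte-like nuclei of Empty, PHF7 and PT. The other reporter sequence, Ai9_SV40, stood at 55.8, 70.4 and 98.7 CPM in fibroblast-like, 229.8, 139.8 and 206 CPM in cardiomyocyte-like and 244, 188 and 318 CPM in endothelial-like nuclei, so neither marked fibroblast-like nuclei. In PMT tdTomato stood at 0 UMIs (under a floor of 24.8 CPM) and 2.34 CPM.

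Cardiac transcripts in fibroblast-like nuclei bear on whether fibroblasts took on cardiomyocyte RNA. After each nucleus was thinned to 1000 UMIs, a UMI of a sarcomere gene (such as Ttn, the giant spring protein of muscle) was found in 31.6% (27.9 to 35.6) of fibroblast-like nuclei in Empty, 34.5% (29.5 to 39.8) in PHF7, 30.7% (25.4 to 36.4) in PT and 51.2% (35.5 to 66.7) in PMT. Thinning left out 50, 16, 27 and 64 shallower nuclei, and PMT kept 43. Unthinned shares were 57.8, 69.6, 55.1 and 57.9%. Endothelial-like nuclei, which should lack these genes, gave 43.9% (35.8 to 52.3), 47.3% (36.9 to 57.9) and 39.8% (30.3 to 49.9) in Empty, PHF7 and PT, at median depths of 2168, 2755 and 2107 UMIs against 2962.5, 3046.5 and 2655 in fibroblast-like nuclei. Macrophage-like nuclei gave 41.9, 53.7 and 48.8%, at 4070.5, 4253 and 4649 UMIs. The fibroblast-like shares of Empty, PHF7 and PT lay at or below those of endothelial-like nuclei and are read as background. For PMT no class had enough thinned nuclei for a background, and its unthinned pericyte-like share was 64.3% (44.1 to 81.4) at a median of 710.5 UMIs, against 864 in fibroblast-like nuclei. With at least 3 UMIs asked for, the shares were 3.20, 4.68, 4.88 and 11.6%, and without Ttn the PMT share was 25.6%.

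Fibroblast-like nuclei of PHF7 against Empty address what PHF7 alone did to scar fibroblasts. Genes of activated fibroblasts were lower in PHF7 and genes of resting fibroblasts higher. Of 11 measured activated genes, 10 were lower, with a median log2 ratio of -1.22, below all 10000 matched random lists as a description of these libraries. Ddah1, which breaks down an inhibitor of nitric oxide synthesis, stood at a ratio of 0.146 (0.0775 to 0.239) and Sfrp2, a secreted Wnt modulator, at 0.240 (0.139 to 0.375). Fap, a surface protease of activated fibroblasts, went the other way at 1.99 (1.73 to 2.28), and Fn1 was at 0.907 (0.748 to 1.09). Of 10 resting genes, 9 were higher, with a median of 0.75, above all random lists. Scara5, a ferritin receptor, stood at 4.28 (3.58 to 5.16) and the lipid transporter gene Abca8a at 2.73 (2.60 to 2.87), while Mfap5 was at 0.639 (0.568 to 0.715). Cluster 6 held 75.0% of the fibroblast-like nuclei of Empty, and cluster 4 held 73.5% of those of PHF7. The nuclei numbered 644 and 358, with 2.22 and 1.22 M UMIs. Mitochondrial transcripts took 0.224, 0.507, 0.860 and 0.671% of UMIs in fibroblast-like nuclei of Empty, PHF7, PT and PMT.

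Matrix genes followed the activated genes in PHF7. All but 1 of 4 late scar genes were lower (median -1.02), among them Comp, a cartilage and tendon matrix protein, at -1.51 and Cilp at -1.04, with Prg4 at 0.27. Only female nuclei held less of this list, at a summed 37.4 CPM (22.5 to 58.4) against 394 (363 to 427) in Empty male and 471 (403 to 548) in PHF7 male nuclei. Of 17 collagen and matrix genes 13 were lower (median -0.52), led by Eln, elastin, which stood at 711 CPM in Empty and 122 CPM in PHF7 (ratio 0.172, 0.144 to 0.203), and by Fbn1, fibrillin, at -1.31, while Dcn, decorin, was higher at 0.89. TGF-beta and YAP targets had 8 of 9 members lower (median -0.71), with Skil at -1.17, and Ltbp1 higher at 1.24. Sarcomere genes had 8 of 10 lower (median -0.57; Myh6 -0.80), calcium and ion handling genes 7 of 9 (-0.33; Jph2 -0.62, Trdn 0.69) and cardiac transcription regulators 5 of 8 (-0.34; Tbx20 -0.65, Esrrg 0.69). The sarcomere difference came from few nuclei, since the mean count of sarcomere UMIs was 6.86 in Empty and 4.42 in PHF7 with a median of 1 in both, and in nuclei thinned to 1000 UMIs the means were 0.687 and 0.877, the other way round. Fatty acid oxidation genes had 9 of 11 higher (0.09; Lpl 0.74, Ppargc1a -0.46). Inflammation genes (-0.52; Nfkbia -0.69, C3 0.41) had 1 of 3 higher, interferon stimulated genes (-0.35; Usp18 -0.45, Stat2 0.18) 2 of 6, and angiogenesis and hypoxia genes (-0.17; Hif1a -0.63, Angpt1 0.28) 1 of 4. The cell cycle list had a single measured gene, Pola1, at 0.63.

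The genes with the largest ratios in PHF7 fibroblast-like nuclei were Mme (ENSMUSG00000027820, mm10 chromosome 3, 63295211 to 63383713), the endopeptidase neprilysin, with 20 UMIs in Empty and 223 in PHF7 (ratio 19.8, 12.8 to 33.8), Lrrtm3, a synaptic adhesion gene (3.73 on the log2 scale), the muscarinic receptor gene Chrm3 (10.6, 7.14 to 16.6) and Tox, a nuclear HMG-box protein (3.24). Gsta3, a glutathione transferase (2.96), Lepr, the leptin receptor (2.75), Enpp2, the enzyme that makes lysophosphatidic acid (2.73), and Lvrn, an aminopeptidase (2.71), followed. Lowest was Arntl (chromosome 7, 113178471 to 113314126), a core factor of the circadian clock, with 138 UMIs in Empty and 3 in PHF7 (ratio 0.0459, 0.00805 to 0.118). Below 1 too were Kif26b (-3.05), Ddah1 (-2.78), the proline transporter gene Slc6a7 (-2.61), Eln (-2.54), Wscd2 (-2.43), the potassium channel gene Kcnma1 (-2.26) and Sybu (-2.15). Set against Empty male nuclei, activated genes stood at -3.28 in PHF7 female nuclei (1 member at 0 UMIs, with the same median at its bound) but at -0.24 (bootstrap over genes -0.84 to 0.44) in PHF7 male nuclei, so the lower level in PHF7 was mostly that of its female nuclei. Resting genes stood at 0.88 and 0.54.

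Fibroblast-like nuclei of PT against Empty address the effect of PHF7 with Tbx5. Here too 10 of 11 activated genes were lower (median -0.80, below all random lists) and 9 of 10 resting genes higher (1.06, above all). Lox, which crosslinks collagen, stood at 0.336 (0.172 to 0.574) and Ltbp2 at 0.376 (0.281 to 0.490), with Fap at 1.58 (1.35 to 1.86). Scara5 stood at 6.02 (5.05 to 7.24) and Clec3b, the plasminogen-binding protein tetranectin, at 4.20 (3.10 to 5.76), with Mfap5 at 0.740 (0.655 to 0.833). Late scar genes had 3 of 4 lower (-0.80), Comp at 0.150 (0.0950 to 0.219) and Cilp at -0.99. Cluster 4 held 80.3% of the PT nuclei, which numbered 314 with 0.952 M UMIs. By sex against Empty male nuclei, activated genes stood at -1.0 (-2.28 to -0.53) in PT male and 0.30 (0.02 to 0.65) in PT female nuclei, and resting genes at 0.79 and 0.77. Late scar genes summed to 129 CPM (94.5 to 172) in PT male and 394 CPM (304 to 503) in PT female nuclei, the latter level with 394 CPM in Empty male nuclei.

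Other lists were less uniform in PT. Collagen and matrix genes divided 8 higher and 9 lower (median -0.21), with Lum, lumican, at 1.11, Dcn at 1.07 and Eln at -2.52. TGF-beta and YAP targets had 7 of 9 lower (-0.58; Skil -1.26, Ltbp1 1.23). All 10 sarcomere genes (-0.51; Ldb3 -1.37, Myh6 -0.97) and all 8 cardiac transcription regulators (-0.36; Myocd -1.21, Gata6 -0.07) were lower, as were 7 of 9 calcium and ion handling genes (-0.55; Pln -1.19, Trdn 0.88). As in PHF7, few nuclei made the sarcomere difference, since mean sarcomere UMIs were 6.86 in Empty and 3.94 in PT with a median of 1 in both, and 0.687 and 0.899 in nuclei thinned to 1000 UMIs. Fatty acid oxidation genes had 8 of 11 lower (-0.15; Ppargc1a -0.82, Lpl 0.68). Inflammation genes (-0.11) had 1 of 3 higher, the complement gene C3 at 1.84. All 5 interferon stimulated genes were higher by little (0.22; Ifit2 0.27), and 3 of 4 angiogenesis and hypoxia genes were higher (0.24; Angpt1 0.46, Hif1a -0.71). Pola1 stood at 0.44.

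The largest ratios in PT belonged to Aox3, an aldehyde oxidase, with 5 UMIs in Empty and 95 in PT (ratio 40.5, 18.3 to 139.6), Inmt, a methyltransferase (37.1, 17.8 to 112), Opcml, a neural adhesion gene (28.2, 20.6 to 40.6), Efemp1, the matrix protein fibulin 3 (16.5, 11.4 to 25.2), and the complement gene C7 (15.3, 13.4 to 17.7; 107 CPM in Empty and 1647 CPM in PT). On the log2 scale, Mme (3.57), Tox (3.31) and Chrm3 (3.27) were high as in PHF7. In PT these were mostly genes of the male nuclei: Aox3, Opcml, C7 and Chrm3 stood at 5.07, 4.82, 3.87 and 3.43 in male and at 1.32, 1.26, 0.67 and 0.39 in female nuclei, each against Empty male nuclei. Lowest was Erg, a transcription factor of endothelium, with 154 UMIs in Empty and 4 in PT (ratio 0.0679, 0.0163 to 0.158). Comp (-2.74), Wscd2 (-2.55), Hs6st2, a heparan sulfate sulfotransferase (-2.55), Eln (-2.52), Tanc2 (-2.26), Smoc1 (-2.09) and Sybu (-2.06) followed.

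Fibroblast-like nuclei of PMT against Empty address the cocktail of all 3 factors, with 107 nuclei and 0.121 M UMIs behind every PMT value. Of 11 activated genes 9 were lower (median -0.91, percentile 0.690 of random lists), Ddah1 at 0.142 (0.00239 to 0.535) and Sfrp2 at 0.177 (0.00297 to 0.669) from 1 UMI each, with Fn1 at 1.67 (1.09 to 2.39) and Fap at 1.58 (1.06 to 2.22). Of 8 resting genes 6 were higher (0.48), Scara5 at 5.90 (4.24 to 7.98) and Abca8a at 1.90 (1.67 to 2.16), with Mfap5 at 0.440 (0.284 to 0.632). All 4 late scar genes were lower (-1.65, or -1.38 with the member at 0 UMIs set to its bound), Cilp at 0.295 (0.0284 to 0.869) from 2 UMIs and Prg4, lubricin, at no more than 0.430. The median over all genes was -0.12 in PMT with CPM and -0.14 with median-of-ratios scaling. This shift was not subtracted from the PMT values given here. Cluster 4 held 63.6% of the PMT nuclei, and the activated and resting medians of the 20 PMT female nuclei against Empty male nuclei were -0.86 (-0.21 with 2 members at their bounds) and 0.15.

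Among matrix and signalling lists of PMT, collagen and matrix genes had 7 higher and 10 lower (-0.30; Col5a1 1.01, Col15a1 0.93, Col5a2 -0.89, Col1a2 -0.81) and TGF-beta and YAP targets 2 higher and 5 lower (-0.39; the growth factor gene Tgfb3 2.32, Ccn2 -1.87). Sarcomere genes had 4 higher and 5 lower (-0.31; Ldb3 0.36, Actn2 0.456, 0.0438 to 1.36, from 2 UMIs), calcium and ion handling genes 4 and 4 (0.11, also with Jph2 at its bound; Kcnd2 1.12), cardiac transcription regulators 5 and 2 (0.17; Esrrg 1.08, Tbx20 -0.96) and fatty acid oxidation genes 5 and 3 (0.09; Hadhb 0.83). Inflammation genes (-0.87, also with Nfkbia at its bound; Nfkb1 -0.87) had 1 of 3 higher. All 4 interferon stimulated genes (-0.52) and all 4 angiogenesis and hypoxia genes (-1.06; Hif1a -1.57) were lower. Pola1 stood at -0.46. Among the largest ratios was that of the kinase gene Camk1d, at 6.92 (6.19 to 7.71). On the log2 scale, the phosphodiesterase gene Pde1c (2.76), Dtd1 (2.70), Scara5 (2.56) and the mitochondrial translation genes Taco1 (2.38) and Lars2 (2.37) were high too. The 8 genes at the low end had 0 UMIs in PMT and 130 to 180 in Empty: BC005561, Cyb5r4, Hand2os1, Gramd1c, Snhg18, Larp1b, Abcb1b and Phtf2, each at most at 0.305, 0.329, 0.350, 0.364, 0.382, 0.404, 0.407 and 0.423 of Empty in this order.

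**Figure D2:**
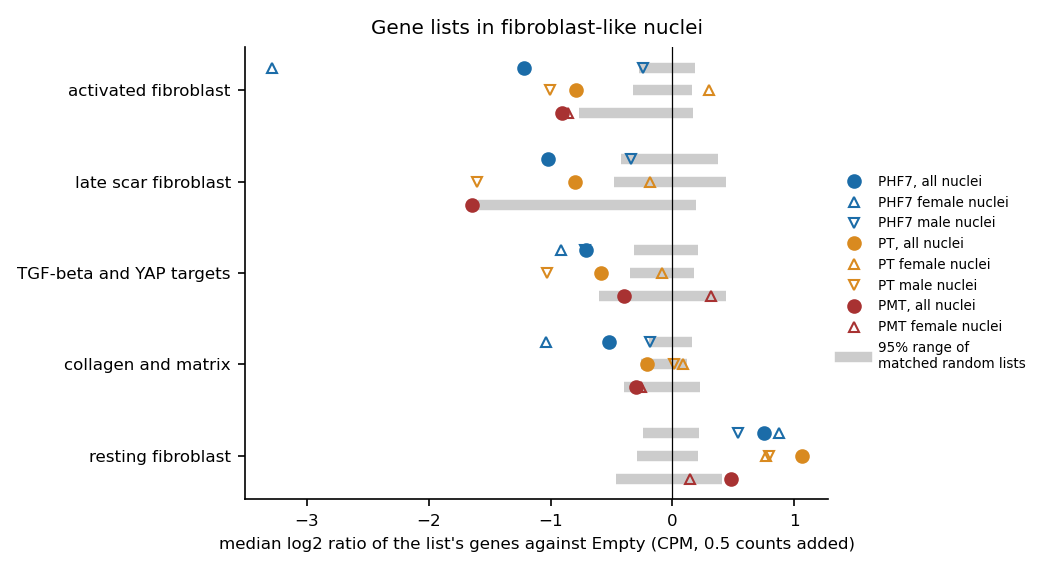
Median log2 CPM ratio of each list in fibroblast-like nuclei against Empty, for all nuclei of a library (filled) and for female and male nuclei against Empty male nuclei (open), with grey bars for the 95% range of 10000 matched random lists. Activated genes lie at -1.22, -0.80 and -0.91 in PHF7, PT and PMT, with PT female nuclei at 0.30, and resting genes lie at 0.75, 1.06 and 0.48.

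Adding Tbx5 to PHF7 is addressed by PT against PHF7 in fibroblast-like nuclei. Collagen and matrix genes were higher in PT (13 of 17, median 0.42, above all random lists), as were markers of fibroblasts (8 of 9, 0.59) and interferon stimulated genes (3 of 4, 0.54). Activated genes had 3 of 7 higher (-0.09), but the sexes went opposite ways, with summed levels of 5844 CPM in PT and 2446 CPM in PHF7 in female nuclei and 3181 and 4811 CPM in male nuclei. Resting genes had 6 of 10 higher (0.10), with 5935 CPM in PT and 6872 CPM in PHF7 in female nuclei and 5720 and 4504 CPM in male nuclei. TGF-beta and YAP targets stood at 0.02, while cardiomyocyte markers were lower in 6 of 7 (-0.29). Adding Mef2c to PT is addressed by PMT against PT. There, resting genes were lower in 8 of 9 (-0.43), activated genes in 5 of 6 (-0.22) and collagen and matrix genes in 9 of 15 (-0.33), while calcium and ion handling genes (4 of 5, 0.85) and cardiomyocyte markers (3 of 3, 0.85) were higher. Free RNA was capped at 6.60% of fibroblast-like RNA in PMT and 7.35% in PT. The cap counts all sarcomere and calcium RNA of these nuclei as free, so it cannot tell their cardiomyocyte markers from background. PMT was also the shallower library.

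Cardiomyocyte-like nuclei of PHF7 against Empty address how surviving heart muscle cells differed. All 8 fetal and stress genes were lower in PHF7, with a median log2 ratio of -1.75, below all 10000 random lists. Nppa, atrial natriuretic factor (chromosome 4, 148000722 to 148002074), stood at 411 CPM in Empty and 51.3 CPM in PHF7 (ratio 0.125, 0.115 to 0.136). Acta1, skeletal actin, stood at 0.0818 (0.0606 to 0.107), Myh7, the slow myosin, at 0.543 (0.525 to 0.562) and Des, desmin, at 0.526 (0.493 to 0.561). Sarcomere genes were lower in 17 of 20 (median -0.35, below all random lists), the most in Actc1, cardiac actin, at 0.333 (0.316 to 0.350), with Myom2 at 1.27 (1.23 to 1.31). The nuclei numbered 922 and 1192, with 9.37 and 13.1 M UMIs, and lay mostly in cluster 2 (56.4%) in Empty and in clusters 0 (34.1%) and 1 (29.6%) in PHF7. TGF-beta and YAP targets were lower in 6 of 9 (-0.89; Ankrd1, a stretch-responsive gene, -1.64, Tgfb2 -1.47, Amotl2 0.56), and all 3 immediate early genes were lower (-0.97; Jun -0.97, Atf3 -4.18, Junb -0.32). Activated fibroblast genes were lower in 5 of 5 (-0.60).

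Several other lists of PHF7 cardiomyocyte-like nuclei had members on both sides of 0. Calcium and ion handling genes had 8 higher and 7 lower (0.16), with the potassium channel genes Kcnj2 at 1.23 and Kcnip2 at 0.55 and the connexin gene Gja1 at -0.59. Cardiac transcription regulators had 6 and 6 (0.06; Prdm16 0.47, Hand2 -1.29), fatty acid oxidation genes 9 and 7 (0.01; Lpl 0.76, Acadm 0.70, Ckm -0.74), interferon stimulated genes 3 and 2 (0.25), inflammation genes 1 and 2 (-0.06) and angiogenesis and hypoxia genes 2 and 4 (-0.12; Fgf2 1.66, Angpt1, a vessel-stabilising growth factor, 2.84-fold, 2.69 to 3.00). Collagen and matrix genes had 2 and 6 (-0.07) and resting fibroblast genes 4 and 4 (0.11). Of the cell cycle list, Cenpf, a kinetochore gene, stood at 3.84 (2.84 to 5.38) and Pola1 at 0.31, too few for a median. Fibroblast markers were higher in 5 of 8 (0.34; 3 of 3, 0.52 without clusters 13 and 15). Endothelial markers were higher in 4 of 4 (1.21), but had too few measured members for a median without clusters 13 and 15. The largest ratios belonged to the water channel gene Aqp4 (3.46), Fmo2 (3.14), Shisa6 (3.01), Cstdc2 (2.92) and Poln (2.73). Fmo2 came with clusters 13 and 15, without which it had 9 UMIs against 6 in Empty (ratio 1.10, 0.357 to 3.84). The lowest belonged to the globin genes Hba-a2 (-4.34), Hbb-bs (-3.95) and Hbb-bt (-3.90), which red blood cells bring, and to the stress-induced factors Nr4a3 (0.0532, 0.0302 to 0.0837) and Atf3 (0.0552, 0.0301 to 0.0891). Without clusters 13 and 15 the globin genes stood at -3.39, -3.08 and -3.01.

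PT against Empty gave a like picture in cardiomyocyte-like nuclei. All 8 fetal and stress genes were lower (median -2.12, below all random lists), with Nppa at 0.177 (0.164 to 0.189), Acta1 at 0.139 (0.111 to 0.172), Myh7 at 0.625 (0.605 to 0.646) and Des at 0.448 (0.418 to 0.479). Sarcomere genes were lower in 14 of 20 (-0.28; Actc1 -1.83, Tnnc1 -1.01, Tnnt2 0.22). Interferon stimulated genes were higher in 5 of 5 (0.84), with Parp14 at 0.98. The compared nuclei include cluster 20, led by interferon-induced GTPase genes, with 44 nuclei in PT and 1 in Empty. The list was not taken without that cluster. Angpt1 stood at 4.93 (4.68 to 5.20), although its list had 4 of 6 lower (-0.26; Egln3 -1.0). TGF-beta and YAP targets were lower in 6 of 9 (-0.45; Ankrd1 -1.63, Ltbp1 0.42), and all 3 immediate early genes were lower (-1.07; Atf3 -5.58, Jun -1.07). The 1715 PT nuclei held 13.6 M UMIs, mostly in clusters 1 (36.3%) and 0 (24.8%).

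Calcium and ion handling genes had 9 higher and 6 lower in PT (0.06; Kcnj2 1.37, Kcnd2 0.92, Jph2 -0.96), fatty acid oxidation genes 9 and 7 (0.14; Acadm 0.82, Ckm -0.68), cardiac transcription regulators 7 and 5 (0.02; Srf -0.92) and inflammation genes 2 and 2 (0.12; C3 1.49). Activated fibroblast genes had 2 and 3 (-0.28; Runx1 1.96), collagen and matrix genes 8 and 2 (0.36; Dcn 0.87) and resting fibroblast genes 6 and 3 (0.76; Scara5 1.99). Markers of endothelium were higher too (4 of 4, 1.44), as were those of fibroblasts (6 of 7, 0.76). Without clusters 13 and 15 the endothelial, resting and collagen lists had too few measured members for a median, and markers of fibroblasts were left with 3 (0.60). Inflammation genes turned to -0.17 without these clusters, with 1 of 3 higher. Cenpf stood at 5.14 (3.83 to 7.16) and Pola1 at 0.68. The largest ratios were those of the potassium channel gene Kcnc2 (37.7, 12.8 to 392), from 2 UMIs in Empty, and Tmem163 (35.2, 11.9 to 366), also from 2. Ano5, a membrane protein gene of muscle (32.4, 16.6 to 86.8), followed, with C7 at 4.16 and Dqx1 at 3.95 on the log2 scale. Kcnc2 and C7 came with clusters 13 and 15: without them Kcnc2 had 0 UMIs against 2 in Empty and C7 stood at 1.80 (0.638 to 6.83), while Tmem163 stood at 27.1 (9.07 to 283), Ano5 at 31.3 (16.1 to 84.0) and Dqx1 at 3.96 on the log2 scale. Tmem163 was among the top genes of cardiomyocyte cluster 19, which held 38 nuclei in PT and 2 in Empty. The lowest were those of Atf3, Nr4a3 (-4.74), Otud1 (-2.95), Fhad1 (-2.89) and Acta1.

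PMT against Empty, the 3-factor cocktail, again had all 8 fetal and stress genes lower (median -2.36, below all random lists). Nppa stood at 0.0443 (0.0329 to 0.0574), Nppb, the B-type natriuretic peptide, at 0.0621 (0.0449 to 0.0823), Flnc at -1.65 and Des at -1.66. The 815 nuclei held 2.99 M UMIs, and cluster 5 held 80.2% and cluster 15 16.2% of them. Nearly all nuclei of these clusters were from PMT. Cluster 5 held 5, 25, 2 and 654 and cluster 15 held 1, 1, 0 and 132 nuclei in Empty, PHF7, PT and PMT. Clusters 0, 1 and 2, large in the other libraries, held 6, 3 and 2 PMT nuclei. Treatment and a library-wide shift cannot be told apart here, with or without cluster 15. Cluster 15 took 29.6% of the UMIs of the 815 PMT nuclei, and 46 of its 92 nuclei that could be called by sex held RNA of both sexes. Genes of other cell types were high in these nuclei: collagen and matrix genes in 11 of 11 (2.36), resting fibroblast genes in 8 of 8 (2.46), fibroblast markers in 8 of 8 (2.18), endothelial markers in 4 of 4 (3.26), pericyte markers in 3 of 3 (1.79) and Schwann cell markers in 3 of 3 (1.81). Without clusters 13 and 15 these lists had too few measured members for a median. Their genes were lower there: Eln stood at 3.8 with cluster 15 and 1.91 without, Scara5 at 3.74 with it and at 3 UMIs against 0 without, Col5a1 at 3.38 and 2.48 and Abca8a at 3.11 and 2.60. The fetal and stress median was -2.14 without these clusters (8 of 8 lower), with Nppa at 0.0528 (0.0380 to 0.0700).

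Muscle genes of the PMT cardiomyocyte-like nuclei depended on the same clusters. Sarcomere genes were lower in 16 of 20 (-0.40; Actc1 -2.09, Tcap -1.88, Tnnc1 0.63) and stood at -0.18 without clusters 13 and 15 (14 of 20 lower). Fatty acid oxidation genes were lower in 11 of 16 (-0.54; Pdk4, which blocks glucose oxidation, 0.166, 0.134 to 0.202; Ppara 2.27, 2.17 to 2.38) and stood at -0.35 without them. Calcium and ion handling genes stood at -0.13 (6 of 15 higher; Kcnip2 0.82, Casq2 -0.95) and 0.08, cardiac transcription regulators at 0.11 (7 of 10 higher; Prdm16 0.92, Hand2 -3.26) and 0.23, and angiogenesis and hypoxia genes at 0.30 (3 of 5 higher; Angpt1 1.28) and -0.01. TGF-beta and YAP targets turned from 0.20 (6 of 11 higher; Tgfb3 5.63, Ankrd1 -2.39, Ccn1 -3.27) to -1.54 (7 of 9 lower). Interferon stimulated genes were higher in 4 of 4 (0.80; Parp14 1.67) and activated fibroblast genes in 2 of 3 (1.71; Fap 3.06), but without clusters 13 and 15 neither list had enough measured members for a median, and Parp14 stood at 1.05 and Ddx58 at a ratio of 0.967 (0.438 to 1.82). Cenpf stood at 2.12, Jun at -1.5 and Atf3 at -1.74. The largest ratio was that of the sodium channel gene Scn1a, with 1 UMI in Empty and 119 in PMT (249.5, 65.6 to 14845). The enzyme gene Padi2 with 3 and 250 UMIs (224, 88.3 to 1274) and the protease gene Tll1 with 3 and 108 (97.1, 37.6 to 555) followed. Next were Rasl12, at 6.13 on the log2 scale, and the signalling gene Wnt2, at a ratio of 68.2 (48.3 to 102.7). Without clusters 13 and 15, the ratio fell to 12.7 (2.83 to 146.6) for Tll1 and to 17.4 (6.90 to 63.1) for Rasl12. It was 219 (56.9 to 13075) for Scn1a, 189 (73.7 to 1075) for Padi2 and 72.6 (50.7 to 111) for Wnt2. The lowest were Sorbs2os (-5.62), Nppa, the globin genes Hbb-bs (-4.49) and Hbb-bt (0.0504, 0.00485 to 0.148, from 2 UMIs), and Nppb.

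**Figure D3:**
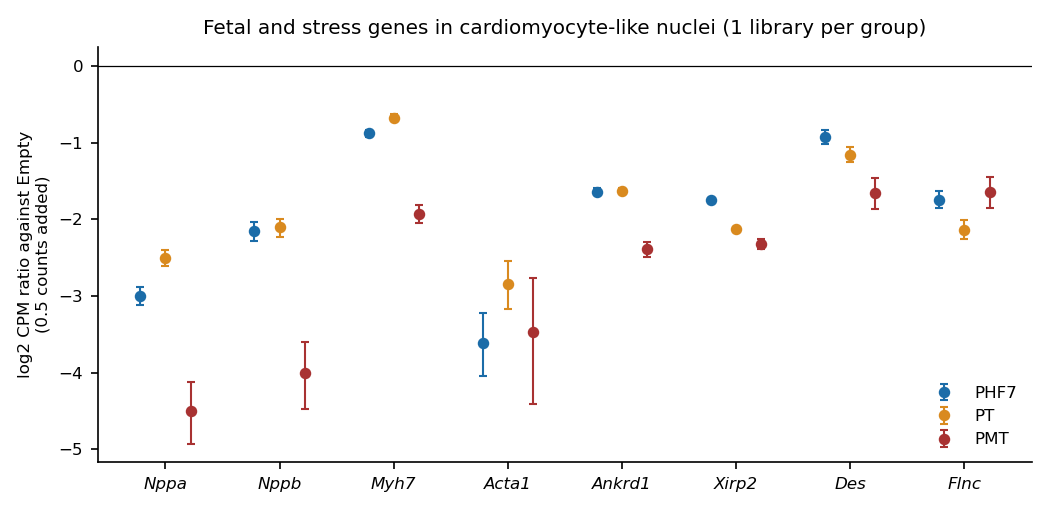
Log2 CPM ratio against Empty of the 8 fetal and stress genes in cardiomyocyte-like nuclei of PHF7, PT and PMT, with whiskers for exact Poisson 95% intervals (counting error only). All points lie below 0, from -0.68 for Myh7 in PT to -4.50 for Nppa in PMT.

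The fetal and stress genes were lower than in Empty male nuclei in female and male nuclei of each treated library. Medians were -2.62 in PHF7 female, -1.14 in PHF7 male, -1.36 in PT female, -2.37 in PT male, -2.27 in PMT female and -1.68 in PMT male nuclei, all below all random lists. Together the 8 genes gave 6934 CPM in Empty male nuclei and 1346, 3487, 3481, 1469, 1397 and 1850 CPM in this order. Male and female nuclei of a library, which come from different hearts, differed in opposite directions, at 1.36 (bootstrap 1.11 to 2.07) in PHF7 and -1.31 (-1.79 to -0.24) in PT, male against female. Between treated libraries, fetal and stress genes stood at 0.03 in PT against PHF7 (5 of 8 higher) and at -0.70 in PMT against PT (7 of 8 lower), the latter at -0.45 (6 of 8 lower, bootstrap -1.77 to 0.03) without clusters 13 and 15. Interferon stimulated genes were higher in PT than in PHF7 (5 of 5, 0.69), and fatty acid oxidation genes lower in PMT than in PT (13 of 16, -0.66; 11 of 16, -0.48 without these clusters).

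Other classes were deep enough for lists in Empty, PHF7 and PT. In macrophage-like nuclei, collagen and matrix genes were lower (median -0.60 in PHF7 and -0.90 in PT) and fatty acid oxidation genes higher (0.48 and 0.69). These nuclei held cardiomyocyte RNA too, with mean sarcomere UMIs of 6.25, 6.25 and 11.7 in Empty, PHF7 and PT after thinning to 1000 UMIs, and 27.0 and 31.1% of those called by sex in PHF7 and PT held RNA of both sexes. In endothelial-like nuclei, endothelial markers stood at -0.28 and -0.14, while cardiomyocyte markers (4.83 and 4.31) and calcium and ion handling genes (3.05 and 3.41) were far higher than in Empty. In pericyte-like nuclei cardiomyocyte markers were lower (-2.03 and -2.91), as were fetal and stress genes (-4.11 and -4.17). These differences came from few nuclei, since mean sarcomere UMIs in pericyte-like nuclei were 94.9 in Empty, 22.6 in PHF7 and 7.28 in PT with a median of 1 in each. In endothelial-like nuclei thinned to 1000 UMIs, the mean count of sarcomere UMIs was 0.595 in Empty, 2.37 in PHF7 and 2.05 in PT while the shares of nuclei with one were near each other, so few nuclei carried the difference.

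Accessibility of gene bodies asked whether chromatin differed where RNA did. In fibroblast-like nuclei activated fibroblast genes were less accessible in PHF7 (12 of 14 lower, median log2 ratio -0.42) and PT (12 of 14, -0.61), both below all random lists, and in PMT (12 of 14, -0.21, percentile 5.79). Among members, chosen after their values were seen, Ddah1 stood at 0.426 (0.306 to 0.575) in PHF7 and 0.434 (0.285 to 0.613) in PT, and Runx1, a transcription factor of activation, at 0.577 (0.453 to 0.727) and 0.527 (0.383 to 0.696). Meox1, a transcription factor of scar fibroblasts, stood at 0.637 (0.488 to 0.812) and 0.549 (0.385 to 0.743). Fap was more accessible in PHF7 at 1.77 (1.09 to 2.80), as its RNA was higher. Late scar genes stood at -0.22 (4 of 7 lower), -0.53 (5 of 6) and -0.36 (5 of 6) in PHF7, PT and PMT, with Comp at -1.0, -1.10 and -0.48. Resting genes, higher in RNA, stood at 0.10 (8 of 11 higher), 0.07 and 0.04. In male nuclei alone, activated genes of PHF7 stood at -0.22.

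Medians of the lists that follow lay between -0.28 and 0.16 in fibroblast accessibility. In the order PHF7, PT and PMT, collagen and matrix genes stood at -0.26, 0.03 and -0.05, sarcomere genes at -0.05, -0.09 and -0.02, calcium and ion handling genes at -0.28, -0.12 and 0.01, and TGF-beta and YAP targets at -0.11, -0.05 and -0.02. Cell cycle genes stood at -0.20 (12 of 14 lower), -0.22 (10 of 14) and -0.15 (9 of 14), inflammation genes at 0.10, 0.16 and -0.07 and immediate early genes at -0.14, -0.07 and -0.12. The most accessible gene relative to Empty in PHF7 was Firre on the X chromosome, where the sexes of the libraries differ, at a ratio of 4.67 (3.21 to 6.98). On the log2 scale, Fam184a (2.08), Bbox1 (1.41), Mypn (1.40) and Cga (1.40) followed. The least were Spata4 (-2.32), Tph2 (-2.31), Slc9a3 (-2.0), Ikbke (-1.95) and Mtln (-1.94). In PT the most accessible on the log2 scale were Vwc2 (1.58), Firre (1.56), Usp33 (1.41) and Six2 (1.41). Among them too was Lepr, whose RNA was high in PHF7, at a ratio of 2.75 (1.57 to 4.71). The least were Rgs5, a pericyte gene (-2.49), Hist1h2bl (-2.32), Palmd (-2.06), Ddx1 (-2.01) and Csf2rb (-1.97). In PMT the most accessible were Myo3a (2.15), Firre (1.89), Rrad (1.66) and Pnck (1.63) on the log2 scale, and Des at a ratio of 2.93 (1.49 to 5.18). At the low end were Matn3 and Lhx2 with 0 counts (intervals up to 0.358 and 0.440). With 2 counts each, Ftsj1 (0.140, 0.00280 to 0.647), Chst15 (0.144, 0.00289 to 0.669) and Minpp1 (0.150, 0.00303 to 0.703) followed.

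In cardiomyocyte-like nuclei all 8 fetal and stress genes had less accessible cardiomyocyte chromatin in PHF7 (median -0.55), PT (-0.60) and PMT (-0.78), below all random lists in each. Acta1 stood at 0.240 (0.193 to 0.295), 0.336 (0.279 to 0.402) and 0.288 (0.234 to 0.349) and Nppa at 0.296 (0.241 to 0.359), 0.387 (0.324 to 0.461) and 0.374 (0.310 to 0.447), members chosen after their values were seen. By sex, the list stood at -0.67 in PHF7 female, -0.21 in PHF7 male, -0.37 in PT female, -0.60 in PT male, -0.79 in PMT female and -0.62 in PMT male nuclei. Sarcomere genes stood at -0.09 (17 of 20 lower), -0.05 and -0.36 (20 of 20). As in RNA, genes of other cells were open in PMT, with fibroblast markers at 2.01 (9 of 9 higher), resting fibroblast genes at 1.01 and collagen and matrix genes at 0.89 (15 of 16). Without clusters 13 and 15 these stood at 0.09, -0.06 and 0.06, sarcomere genes at -0.06 and fetal and stress genes at -0.47 (8 of 8 lower).

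The remaining lists in cardiomyocyte-like nuclei, in the order PHF7, PT and PMT, stood at 0.07, 0.10 and -0.14 for fatty acid oxidation, 0.04, 0.07 and 0.04 for cell cycle, 0.06, -0.08 and 0.22 for immediate early genes and -0.06, -0.23 and -0.37 for neural and skeletal muscle genes, the off-lineage control, which had too few measured members in RNA. Markers of dendritic cells stood at 0.17, 0.04 and 0.19, of mesothelium at -0.11, 0.09 and 0.26, of B cells at -0.14, -0.04 and -0.25, of T or NK cells at -0.17, -0.02 and -0.28, of adipocytes at -0.01, -0.03 and -0.22, of lymphatic endothelium at -0.17, -0.19 and -0.00 and of smooth muscle at -0.13, -0.08 and 0.09. Macrophage markers stood at 0.30 in PMT, and neutrophil markers had too few measured members. Counts in shared regions behind these values were 19594509, 23103722, 24458608 and 22632165 in Empty, PHF7, PT and PMT for cardiomyocyte-like and 5658705, 2264144, 1475863 and 776073 for fibroblast-like nuclei.

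**Figure D4:**
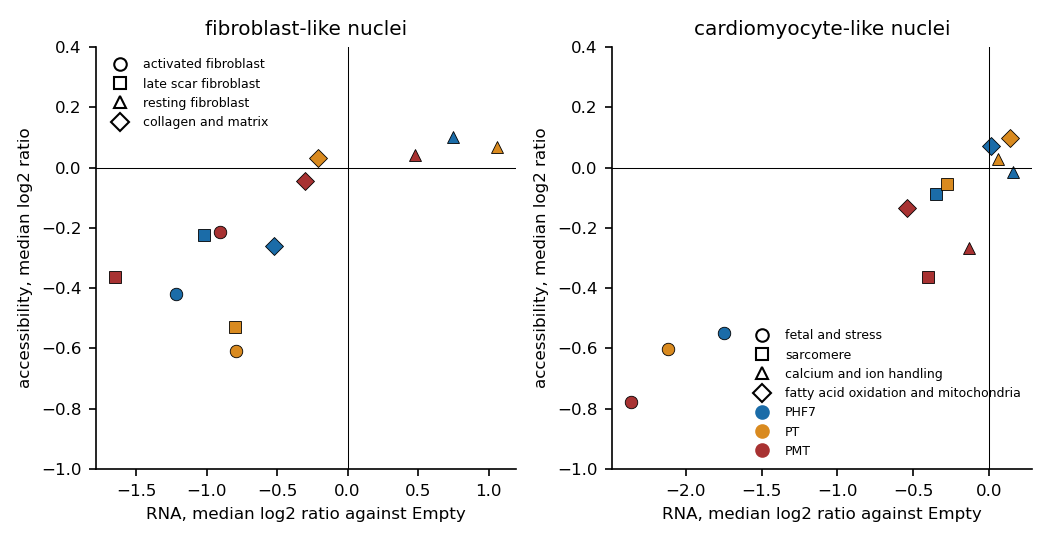
Median log2 ratio against Empty of RNA (x axis) and accessibility (y axis) for 4 lists in fibroblast-like (left) and cardiomyocyte-like nuclei (right), by library (colour) and list (shape). Activated genes lie below 0 on both axes in each treated library (PT -0.80 and -0.61), as do fetal and stress genes (PT -2.12 and -0.60), and resting genes lie above 0 in RNA and between 0.04 and 0.10 in accessibility.

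Peaks called in each library asked how much of the open chromatin was shared. The libraries held 113144, 106277, 117804 and 98110 peaks over 97.1, 91.4, 101.5 and 84.5 Mb in Empty, PHF7, PT and PMT. Of the treated libraries' peaks, 88.3% (88.1 to 88.4) of PHF7, 81.6% (81.4 to 81.8) of PT and 91.0% (90.8 to 91.1) of PMT overlapped an Empty peak. Merged, they made 142375 regions, of which 81121 had a peak in all 4 libraries and 29216 in 1, and the shared regions took 90.9, 93.3, 90.9 and 95.1% of peak counts. Peaks that did not overlap Empty numbered 12485, 21642 and 8879 and held a count in a median of 2.34, 1.57 and 2.46% of nuclei, against 5.28, 3.74 and 5.57% for the others. Among peaks with a count in at least 2% of nuclei, 91.1% of PT's overlapped Empty.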

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

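The tests on hearts and on the sex of the animals below were chosen after the results were seen. The activated fibroblast list went in opposite directions in the sexes of the PT library. Against Empty male nuclei, its median log2 ratio was 0.30 in PT female nuclei (8 of 10 members higher) and -1.0 in PT male nuclei (9 of 10 lower). The difference itself was not tested, since each sex is 1 set of nuclei from an unknown number of hearts.

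Activated genes in fibroblast-like nuclei and fetal and stress genes in cardiomyocyte-like nuclei were lower in each treated library than in Empty. The tables argue against the sex of the animals as the cause for the activated list in PT, where male nuclei against Empty male nuclei gave -1.0 (bootstrap -2.28 to -0.53), and for the fetal and stress list, where the highest of the 3 male medians was -1.14 (-2.18 to -0.68). In PHF7 the effect of sex on the activated list stays open. Male nuclei gave -0.24 (-0.84 to 0.44), an interval that holds both 0 and a clear difference. These bootstrap intervals show the spread between the genes of a list alone and leave out differences between hearts. Treatment and a difference between the pooled hearts cannot be told apart for either list: male against female nuclei of one library gave 0.81 in PHF7 and -0.69 in PT for the activated list, on 4 and 3 measured genes, while on the 10 genes measured against Empty male nuclei the female and male nuclei lay further apart (-3.28 and -0.24 in PHF7, 0.30 and -1.0 in PT), against library differences of -1.22 and -0.80, and up to 1.36 (1.11 to 2.07) for the fetal and stress list, where the highest of the 6 sets of nuclei still lay at -1.14. This stays open because each group is 1 pooled library, so treatment, hearts and library preparation cannot be separated. Empty also holds male hearts alone, so not even the sexes of control hearts could be compared. A treatment effect remains a hypothesis.

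A cluster led by the airway genes Bpifa1, Scgb1a1 and Cyp2f2, left without a name and used in no comparison, held 3.85% (3.22 to 4.57) of PT nuclei, 0.556% of Empty and 0 of 2185 and 0 of 999 nuclei in PHF7 and PMT (at most 0.169 and 0.369%). It stood out because its share in PT lies above that of the control library. Of PT nuclei called by sex, 59 of 1219 male and 0 of 808 female nuclei lay in it, and 60 of its 119 PT nuclei called by sex held RNA of both sexes.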

How the results depend on the processing

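The alternatives with male nuclei alone, without nuclei with RNA of both sexes, without clusters 13 and 15, with RNA thinned to 1000 UMIs in the class ratios and with gene ends alone were chosen after the results were seen. Of 202 alternative values over 30 results, 150 stayed within their interval, 52 moved and 0 reversed. For list medians the interval is the bootstrap over genes. Only list medians could reverse, since class shares, sarcomere shares and peak overlaps have no sign. Female nuclei alone were not among the alternatives, and the activated list stood above Empty male nuclei in PT female nuclei (0.30). The 24 values of the fetal and stress list in cardiomyocyte-like RNA all stayed, from -1.77 to -1.14 in PHF7, -2.37 to -1.74 in PT and -2.44 to -1.68 in PMT. In fibroblast-like RNA 64 of 66 stayed, with activated genes from -1.47 to -0.24 in PHF7, -1.0 to -0.62 in PT and -1.06 to -0.49 in PMT. The 2 that moved were male nuclei alone, at -0.24 for activated genes in PHF7 and 1.40 for resting genes in PMT, from 5 nuclei, too few to show a change. In accessibility, male nuclei alone gave -0.22 for activated genes and -0.21 for fetal and stress genes in PHF7, and leaving out clusters 13 and 15 gave -0.47 for fetal and stress genes in PMT, while 32 others stayed. For the values that moved, here and below, the cause was not tested.

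Class shares (%) moved in 29 of 56 values. The fibroblast-like share at Leiden resolution 2 was 21.1, 7.05, 4.71 and 4.004 in Empty, PHF7, PT and PMT, and at resolution 0.5 11.2 in PT and 20.9 in PMT. With at least 1000 UMIs and 2000 peak counts it was 22.9, 14.2, 6.80 and 5.09. With all deposited barcodes it was 10.7 in PT and 2.95 in PMT, without doublet removal 6.16 in PMT, and from clusters of the peak counts 28.8 in Empty, 12.3 in PT and 13.4 in PMT. The cardiomyocyte-like share at resolution 0.5 was 52.4, 50.1 and 71.7 in PHF7, PT and PMT, and at resolution 2 68.4 in PMT. With at least 1000 UMIs and 2000 peak counts it was 40.2, 58.0, 57.5 and 89.4 in Empty, PHF7, PT and PMT. With all deposited barcodes it was 52.3, 48.1 and 46.8 in PHF7, PT and PMT, without doublet removal 86.0 in PMT, and from clusters of the peak counts 69.1 in PMT.

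The share of fibroblast-like nuclei with a sarcomere UMI moved in 12 of 15 values. Thinned to 2000 UMIs it was 45.4, 56.1 and 44.4% in Empty, PHF7 and PT, with no value for PMT, whose nuclei are too shallow. With at least 3 UMIs it was 3.20, 4.68, 4.88 and 11.6%, without Ttn 26.8, 26.3, 23.0 and 25.6%, and with 3 times the doublets removed 27.6% in Empty. Peaks overlapping Empty moved in 6 of 6 values, to 88.0, 81.3 and 90.7% in PHF7, PT and PMT with overlap of at least 1/2 of both peaks, and to 89.0, 91.1 and 90.7% among peaks with a count in 2% of nuclei.

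Neither motif alternative was run, since no genome sequence was at hand, and male fibroblast-like nuclei of PMT were too few for an accessibility value. No paired analysis was possible because each group is 1 library. Depth limits PMT fibroblast-like nuclei, with 0.121 M UMIs, to large ratios.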

Other observations

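The 5-gene test below was chosen after the results were seen. Some clock genes differed between libraries in fibroblast-like nuclei, beyond the named gene Arntl. In PHF7 against Empty, Hlf, a clock-controlled transcription factor, stood at 3.78 (3.06 to 4.72), the clock repressors Per2 and Per3 at 2.91 (2.27 to 3.75) and 2.80 (2.35 to 3.34), Dbp at 2.04 (1.40 to 2.98) and Cry1 at 7.07 (3.90 to 14.6), while Npas2, a partner of Arntl, stood at 0.456 (0.281 to 0.697). Others differed little: Nr1d1 stood at 0.773 (0.561 to 1.05), Bhlhe41 at 0.887 (0.616 to 1.25), Per1 at 1.21 (0.885 to 1.64) and Nr1d2 at 1.18 (1.05 to 1.32). The genes that differed were picked after their values were seen.

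Cardiomyocyte-like cluster 20, led by interferon-induced GTPase genes, held 44 of 3273 PT nuclei (1.34%, 0.978 to 1.80). It held 4 of 2185 in PHF7, 3 of 999 in PMT and 1 of 2516 in Empty. Of its PT nuclei, 27 were called male and 1 female, and 10 held RNA of both sexes. Unnamed cluster 3, with markers of several classes, held 375, 218, 258 and 0 nuclei in Empty, PHF7, PT and PMT. They held 3.62 times the median UMIs of their libraries, and 190 of 217 nuclei called by sex in PHF7 and 166 of 246 in PT held RNA of both sexes, as multiplets do.

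Arntl stood at 0.0459 (0.00805 to 0.118) in fibroblast-like nuclei of PHF7 against Empty. A different time of day at harvest would shift the clock of all cells of a heart alike. The tables argue against it as the whole cause for Arntl in PHF7, which was higher in cardiomyocyte-like nuclei, at 3.33 (2.24 to 5.28), and stood at 0.906 (0.557 to 1.43) in macrophage-like and 0.449 (0.138 to 1.13) in endothelial-like nuclei, while the arm of Arntl without the gene itself minus the arm of the Per genes gave 0.31 in cardiomyocyte-like and -1.90, from Npas2 and Clock alone, in fibroblast-like nuclei. Arntl RNA was scarce in cardiomyocyte-like nuclei, with 28 UMIs in Empty (2.99 CPM, against 62.1 CPM in fibroblast-like nuclei) and 132 in PHF7. A shift shared in part between classes stays open. Arntl in PT was lower in fibroblast-like (0.311, 0.175 to 0.499), endothelial-like (0.105, 0.00172 to 0.459) and macrophage-like nuclei (0.474, 0.253 to 0.811). Per2 in PHF7 was higher in endothelial-like (2.36, 1.54 to 3.74), macrophage-like (2.24, 1.52 to 3.36) and cardiomyocyte-like nuclei (1.24, 1.12 to 1.36) too. In endothelial-like and macrophage-like nuclei of PHF7, Per3 (1.78, 1.11 to 2.92, and 1.53, 1.13 to 2.05) was also higher. So was Tef (1.55, 1.07 to 2.26, and 1.61, 1.30 to 2.00), while Clock was lower (0.625, 0.406 to 0.935, and 0.762, 0.598 to 0.961). Dbp, Npas2, Per1, Nr1d1, Nr1d2, Ciart and Bhlhe41 did not differ beyond their intervals in either class. In cardiomyocyte-like nuclei of PHF7, Hlf (1.90, 1.67 to 2.17), Per3 (1.42, 1.30 to 1.55), Cry1 (1.52, 1.25 to 1.88) and Tef, of the Per arm (1.73, 1.63 to 1.83), were also higher. Others there were lower, namely Dbp (0.820, 0.695 to 0.969), Ciart (0.690, 0.588 to 0.810), Bhlhe41 (0.761, 0.628 to 0.921) and Nr1d1 (0.769, 0.588 to 1.01). A difference between the pooled hearts stays open and untested, and a treatment effect on the fibroblast clock is a hypothesis.

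The 50 genes with the largest ratios in cardiomyocyte-like nuclei of PMT had a median log2 ratio of 4.51. For the genes Scn1a, Wnt2, Hydin, Cnga1 and Iqank1, 5 of the 50, the tables argue against RNA of fibroblasts and other cells in multiplets, since their level lay above that in fibroblast-like and in all other nuclei of PMT, such as 229 CPM (212 to 247) against 38.2 for Wnt2. For the other 45, multiplets cannot be told apart from RNA of the cardiomyocytes: the median over the 50 was 3.42 (3.13 to 3.72; 3.38 with the gene at 0 at its bound) without clusters 13 and 15 and nuclei with RNA of both sexes, above the limit of 3 set before, but that limit was wrong, since only 408 of 815 nuclei could be called by sex and nuclei of the same sex joined together go unseen. Within PMT, 46 of the 50 were higher in cluster 15, where nuclei often held RNA of both sexes, than in cluster 5. The median log2 ratio of cluster 15 to cluster 5 was 4.12 over the 50 and 4.15 over the 45. A library-wide technical change of the RNA counts stays open for all 50, at 1.32 (0.93 to 1.73) in fibroblast-like nuclei, and an accessibility median of 0.49 (0.27 to 0.83) does not decide it. A treatment effect remains among the open explanations, since PMT is 1 shallow library.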
